A study of Mus musculus with 12 samples.

How the data were processed

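RNA sequencing was performed on spinal cord of 3-month-old C57BL6 mice from 3 genotype groups of 4 mice each, 12 mice in all. Control mice carried floxed Tardbp alleles and no Cre. Mice called cHet carried Gfap-Cre, a recombinase driven by the astrocyte gene Gfap, with a single floxed allele, and mice called cKO carried Gfap-Cre with both alleles floxed. Tardbp encodes TDP-43, an RNA-binding protein of the nucleus. By their labels each group held 2 males and 2 females, and each library came from a separate mouse. Per the labels' protocols, cords were frozen in liquid nitrogen, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit. The labels give no batch, litter or sequencing date. The level of the cord that was sampled, and whether the kit marked strand, are not given in the sources used here.

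The expression values were the authors' normalized TPM per gene (transcript abundance scaled for transcript length and library), deposited as a signal that is never negative, in a table of 36121 Ensembl genes by 12 mice. Per the submitters' processing notes the tools were kallisto 0.44.0 and sleuth 0.30.0 with the GRCm38 genome; the annotation release and filters are not given in the sources used here. The deposited values of a library summed to between 954895 and 1048381 and not to the same total, so the authors' signal carries a scaling between libraries. TPM keeps no sequencing depth, so read depth is unknown, and no counting interval or floor is given. The authors also deposited a table for each pair of groups with p-values and q-values from a likelihood ratio test and a Wald test, an effect estimate and variance components. The slope of the authors' deposited effect estimate on the difference of natural log TPM was 0.846 for cKO against control, which is nearer to a natural log scale than to log2; its size is not used here. From the variance that the authors' deposited tables attribute to the estimation of abundance, the median technical error of a gene was 15.8% at a mean of 1 to 5 TPM, 6.83% at 5 to 20 TPM, 4.04% at 20 to 100 TPM and 1.91% at 100 TPM or more, if that variance is on the natural log scale.

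Genes with a mean of at least 1 TPM over the 12 mice were kept (15259 genes), and 0.5 was added before the log2 transform, so that a fold change is on the log2(TPM + 0.5) scale and understates the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend, two-sided), with all 12 mice in the fit, no covariate and Benjamini-Hochberg adjustment within a comparison. Genes are called at an adjusted p under 0.05. A rise or a fall is written only of a called gene or list. Mean levels are arithmetic means of TPM with their SD over 4 mice, and each SE is that of limma. Single values per library were compared with a two-sided exact permutation test over all 70 assignments of 8 libraries, for which the smallest possible p is 0.0286. The limma step was tested on simulated log2 values with the means and spreads of these genes. For cKO against control, over 15259 genes of which 50 were changed by each size, it recovered 32% of changes of 0.25, 82% of 0.5, 96% of 1 and all 50 of 2 on the log2 scale, with 15 false calls.

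The tests, the groups, 29 gene lists and the rule for naming genes were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists within a comparison. List members that were absent or below the expression filter were not tested, and counts are out of the measured members. Camera with an estimated correlation and fry, a self-contained test of whether a list's genes move on balance one way, were alternatives. Per comparison the rule names Tardbp and Gfap, up to 10 rises and 10 falls with the largest fold change among called genes whose 4 libraries of each group do not overlap, and up to 4 called members of each list by adjusted p, or the 2 members with the smallest p, as values, where none was called. The results of some genes that the rule takes are not reported here, and these genes stay in the counts of called genes and lists. Genes with only a clone or predicted name are counted and not named, and where fewer than 5 genes were called the 5 with the smallest p are named. From the authors' deposited tables up to 5 genes per direction are named by q. Gene coordinates come from the GENCODE M21 annotation of GRCm38, which holds 35471 of the 36121 deposited identifiers; 650 identifiers are not in it.

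Of those, 411 carry the symbol of a single reference gene, as copies on alternate scaffolds do, and 166 such rows passed the expression filter. An aligner of transcripts can split reads between such copies. Rows were fitted as deposited, as fixed in advance, and each list uses the reference row of a symbol. Adding the copies to their reference row was chosen as an alternative after the data were examined. Among the genes named, Trem2 and Clcf1 have a copy row, so their levels are uncertain.

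The alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter, a mean of at least 5 TPM, median-of-ratios rescaling, rescaling to equal totals without the mitochondrially encoded genes, sex as a covariate, a fit of only the 2 groups compared, robust eBayes and leaving out each library in turn. Removing a trend on transcript length in each library, and a test of the sex interaction without control replicate 1, were added after the data were examined. The nuclear oxidative phosphorylation genes (79 genes by symbol pattern) and the lists in the last part of the text were also chosen then. No transcript-level table was used here, so the planned tests per transcript and of isoform usage were not run, and neither were count models.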

Results

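Spinal cord RNA was profiled in 12 mice to ask how deletion of Tardbp in Gfap-Cre cells alters gene expression in the cord, with 4 control, 4 cHet and 4 cKO mice. The libraries were alike in breadth, with 15188 to 15384 genes at 1 TPM or more. Pearson's r between log2 values of any pair of libraries, across genes that are not independent replicates, lay between 0.980 and 0.987. No pair of libraries held identical values. The first principal component held 15.1% of the variance and placed all 4 cKO libraries above all others. The sum of normalized TPM was 967165 ± 12164 (SD, n = 4) in control, 1002460 ± 18688 in cHet and 1031670 ± 12645 in cKO. It was higher in cKO and in cHet than in control (exact permutation p = 0.0286 each, the smallest possible).

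Tardbp, the deleted gene (ENSMUSG00000041459, chromosome 4, 148612382 to 148627019, minus strand), was measured at 171 ± 6.73 TPM in control, 170.4 ± 8.64 in cHet and 148 ± 5.06 in cKO (SD, n = 4). Single control libraries held 181, 167, 169 and 166 TPM, cHet libraries 178, 173, 172 and 158, and cKO libraries 150.3, 150.2, 151 and 140.5, all 4 below every other library. The level in cKO was lower by a log2 change of -0.20 ± 0.04 (SE) against control (limma adjusted p = 0.0113; exact permutation p = 0.0286). Against cHet the log2 change was also -0.20 (limma adjusted p = 0.0158), and without cKO replicate 4 that adjusted p was 0.0522. The cHet libraries did not differ detectably from control (log2 change -0.00 ± 0.04, limma adjusted p = 0.984; exact permutation p = 0.971). The values are for whole cord, in which cells without Cre also express Tardbp, and the labels do not say which exons are floxed, so a gene-level TPM can include RNA of the recombined allele.

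**Figure D1:**
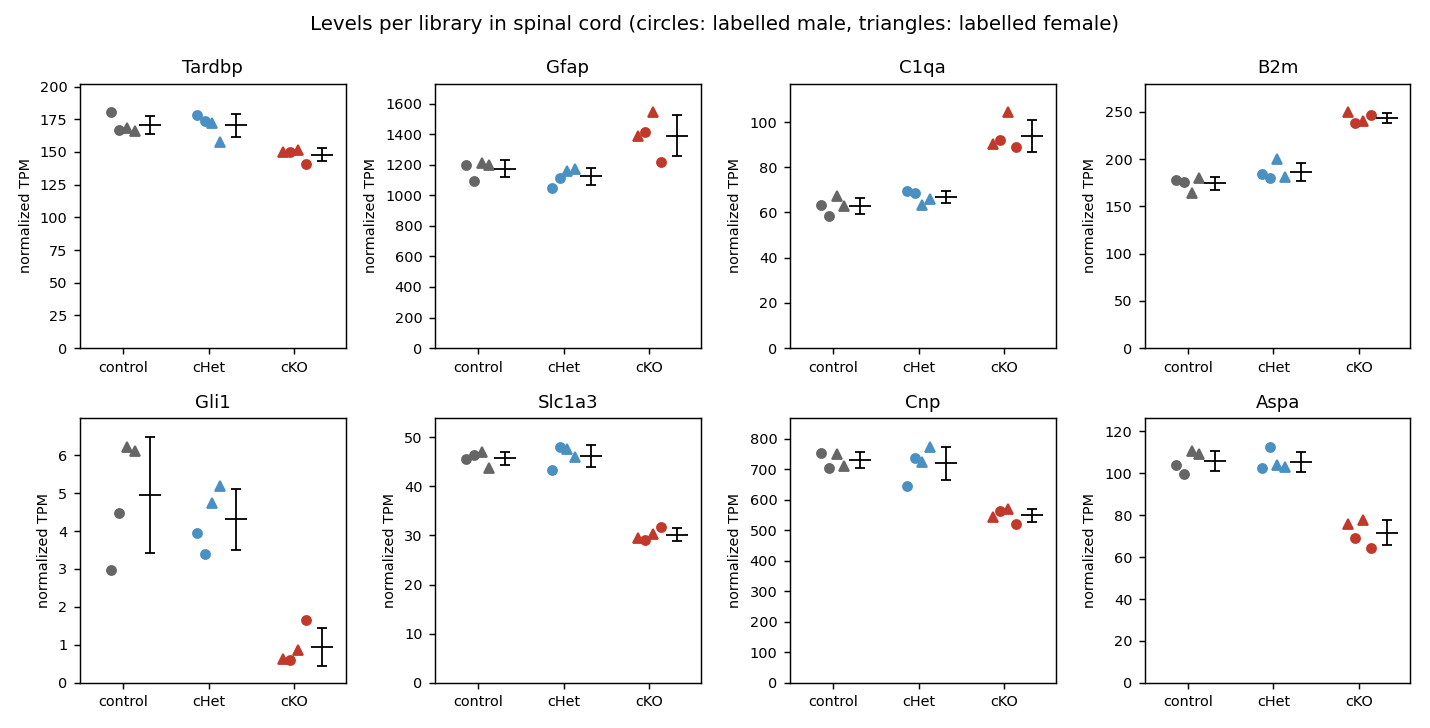
Normalized TPM (vertical axes, from 0) of 8 genes in each library of control, cHet and cKO mice (circles labelled male, triangles labelled female); the black mark and bar give the mean and SD of 4 libraries. Tardbp averaged 171 TPM in control and 148 in cKO, C1qa 63.0 and 93.9, Gli1 4.94 and 0.944, and Cnp 730.5 and 549.

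The comparison of cKO with control asked what changed when both Tardbp alleles were deleted in Gfap-Cre cells. Of 18 astrocyte genes 5 rose and 4 fell, some microglial, complement and antigen presentation genes rose, and 11 of 20 myelin genes fell (myelin list adjusted p = 0.0835 with an estimated correlation). The largest rise was that of Qprt, a gene of NAD synthesis from quinolinate, from 1.08 ± 0.367 to 4.38 ± 0.569 TPM (SD, n = 4). The largest fall was that of Gli1, a transcription factor and target of hedgehog signalling (chromosome 10, 127329882 to 127341974), from 4.94 ± 1.53 to 0.944 ± 0.491 TPM. Limma called 1374 of 15259 genes, 878 higher and 496 lower in cKO. Of these, 150 changed by at least 1.5-fold (97 higher, 53 lower), and the median size of a called change was 0.27 on the log2 scale. The split by direction depended on the scaling, with 699 higher and 575 lower after median-of-ratios rescaling and 463 higher and 814 lower after rescaling without mitochondrially encoded genes. The count was 814 without cKO replicate 2, 890 without cKO replicate 4 and 907 without control replicate 2.

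Among the other largest rises were Slc25a34, a mitochondrial carrier gene (log2 change 1.56 ± 0.14, SE) and the metalloprotease gene Adamts9 (1.38 ± 0.11). The secreted peptidase gene Pm20d1 rose from 3.67 ± 0.605 to 11.3 ± 1.84 TPM. Cox7a1, which encodes a subunit of cytochrome c oxidase, rose from 50.2 ± 6.75 to 131 ± 11.8 TPM (SD, n = 4). Hsd11b1, whose enzyme regenerates active glucocorticoid, rose from 36.1 ± 1.51 to 78.5 ± 5.84 TPM with the smallest limma adjusted p of the named genes (2.31e-06). Gpnmb rose by 1.21, Acox2 by 1.20, Plac9b by 1.20 and Igfbp2 by 1.08 on the log2 scale. Falls included Etnppl, a gene of phosphoethanolamine breakdown (log2 change -1.39 ± 0.17), Itih3 (-1.18 ± 0.08), the galectin gene Lgals3 (-1.45 ± 0.33), the melanocortin receptor gene Mc5r (-1.44 ± 0.25), Klri1 (-1.15 ± 0.22), Rasal1 (-1.09 ± 0.12) and the leptin receptor gene Lepr (-1.03 ± 0.23). Ptgds, the gene of prostaglandin D synthase, fell from 1004 ± 134 to 494 ± 41.6 TPM, and A2m from 25.4 ± 1.38 to 12.6 ± 1.53 TPM (SD, n = 4). For these 20 genes limma adjusted p values lay at or below that of Lgals3, 0.0188; the call of Lgals3 was lost in 4 of 23 alternatives and that of Lepr in 2 of 22 (highest adjusted p 0.0567 and 0.0545).

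Astrocyte genes did not move as a block. Of 18 measured, 5 rose and 4 fell (8 and 4 when adjusted over the list alone). Atp1b2, a sodium pump subunit, rose from 569.7 ± 18.8 to 859 ± 43.7 TPM (SD, n = 4), and the glutamate transporter gene Slc1a2 rose from 322 ± 5.20 to 397 ± 7.63 TPM. Acsbg1 rose by 0.38 on the log2 scale. Slc1a3, the other main astrocytic glutamate transporter gene, fell by 0.59 ± 0.04 on the log2 scale, to 30.2 ± 1.23 TPM (limma adjusted p = 1.53e-05). The list as a whole had a camera adjusted p of 0.0282, and adjusted p = 0.307 with an estimated correlation.

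Gfap, the gene of the astrocyte intermediate filament (chromosome 11, 102887336 to 102900912), rose from 1175 ± 55.5 to 1391 ± 135 TPM in cKO (SD, n = 4; log2 change 0.24 ± 0.06, limma adjusted p = 0.0386). That call was lost in 11 of 23 alternatives (range of adjusted p 0.00747 to 0.110), with the sign kept. Among these, the adjusted p was 0.0525 after median-of-ratios rescaling, 0.0647, 0.110, 0.0634 and 0.0692 without control replicates 1, 2, 3 and 4, and 0.0751, 0.0962 and 0.0954 without cKO replicates 1, 2 and 3. Of 12 pan-reactive astrocyte genes 4 rose and none fell (5 adjusted over the list alone; camera adjusted p = 0.00171), with Serpina3n at 37.0 ± 2.23 and 52.1 ± 4.50 TPM, Hspb1 at 50.1 ± 2.82 and 66.2 ± 4.29 and Aspg at 8.31 ± 0.861 and 12.3 ± 0.739 in control and cKO. Of 11 A1-type genes, defined from astrocytes exposed to inflammation, 4 rose and none fell (7 adjusted over the list alone; camera adjusted p = 0.000171). The 4 were H2-D1, H2-T23, Psmb8 and Serping1, which belong to antigen presentation and complement control and are also expressed outside astrocytes. The rise of H2-D1 was 0.30 ± 0.04 on the log2 scale, and the calls of Psmb8 and Serping1 were each lost in 8 of 23 alternatives and that of H2-T23 in 3. Among 8 A2-type genes only Emp1 was called (log2 change 0.58 ± 0.10; 2 higher adjusted over the list alone; camera adjusted p = 0.516).

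Of 13 homeostatic microglia genes 7 rose and none fell (10 adjusted over the list alone; camera adjusted p = 8.91e-07), with Fcrls at 8.13 ± 0.809 and 14.5 ± 1.88 TPM in control and cKO (SD, n = 4). Cx3cr1 rose by 0.27 and Selplg by 0.30 on the log2 scale, the latter call lost in 1 of 23 alternatives. Of 18 genes of disease-associated microglia 8 rose (Ctsd, B2m, Tyrobp and Gpnmb first by adjusted p) and Lgals3 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.05e-05). Complement genes rose in 5 of 10 cases (5 adjusted over the list alone; camera adjusted p = 0.000103). C1qa rose from 63.0 ± 3.52 to 93.9 ± 7.17 TPM, C1qb from 62.1 ± 2.54 to 90.2 ± 3.00 and C1qc from 50.1 ± 3.26 to 69.3 ± 3.12, and C3 rose by 0.47 on the log2 scale. MHC class I presentation genes rose in 6 of 11 cases (8 adjusted over the list alone; camera adjusted p = 3.21e-07), with B2m at 174 ± 6.95 and 244 ± 5.46 TPM and H2-K1 at 41.2 ± 1.21 and 53.5 ± 4.60 TPM. With an estimated correlation the pan-reactive, A1-type, disease-associated microglia, complement and MHC class I lists had an adjusted p of 0.0328 each, and the homeostatic microglia list 0.0473. H2-D1, H2-T23 and Psmb8 are in both the A1-type and MHC class I lists, and Serping1 is in the A1-type and complement lists. B2m is in the disease-associated microglia and MHC class I lists, so the list p values are not independent. Interferon response genes rose in 6 of 19 cases (12 adjusted over the list alone; camera adjusted p = 8.91e-07, and adjusted p = 0.133 with an estimated correlation), with Ifi27 higher by 0.61 ± 0.06 on the log2 scale and Ifit1, Oasl2 and Lgals3bp also called. Of 15 inflammatory cytokine and NF-kB genes only 8 were measured, and none of these was called (camera adjusted p = 0.404). The log2 differences were 0.93 ± 0.45 for Cxcl10 and 0.18 ± 0.10 for Nfkb2.

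Genes of mature oligodendrocytes and myelin fell in 11 of 20 cases and rose in none (17 lower adjusted over the list alone), with a median log2 change of -0.30 (camera adjusted p = 1.26e-13, and adjusted p = 0.0835 with an estimated correlation). Cnp, a myelin enzyme gene, fell from 730.5 ± 25.8 to 549 ± 21.7 TPM (SD, n = 4), Aspa from 106 ± 4.97 to 71.8 ± 5.95 TPM, and Opalin from 53.4 ± 3.75 to 34.2 ± 3.20 TPM. Myrf, the transcription factor of myelination, fell by 0.37 on the log2 scale. Precursor and newly formed oligodendrocyte genes fell in 2 of 14 cases, Bcas1 and Enpp6 (3 adjusted over the list alone; camera adjusted p = 0.00675, and adjusted p = 0.256 with an estimated correlation). The calls of Enpp6 and Bcas1 were lost in 9 and 6 of 23 alternatives (highest adjusted p 0.109 and 0.0845). Cholesterol synthesis genes fell in 3 of 23 cases, Stard4, Srebf2 and Fdft1 (10 adjusted over the list alone; camera adjusted p = 6.14e-07, and adjusted p = 0.254 with an estimated correlation). Fdft1, of squalene synthesis, was at 65.8 ± 4.88 TPM in control and 55.2 ± 1.99 in cKO, a call lost in 6 of 23 alternatives, and that of Srebf2 was lost in 3 (highest adjusted p 0.0683 and 0.0610).

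Mitochondrially encoded genes made up 17.3% ± 1.08 of summed TPM in control, 17.2% ± 0.886 in cHet and 19.6% ± 0.689 in cKO (SD, n = 4; cKO against control exact permutation p = 0.0286). They rose in 8 of 13 cases (10 adjusted over the list alone; camera adjusted p = 9.48e-09, and adjusted p = 0.211 with an estimated correlation), with mt-Nd2 at 7742 ± 586 and 10834 ± 318 TPM in control and cKO. The transcripts mt-Nd6, mt-Nd5 and mt-Nd4l rose by 0.55, 0.54 and 0.40 on the log2 scale. The mean log2(TPM + 0.5) of 79 nuclear oxidative phosphorylation genes, chosen after their values were seen, was 8.12 in control, 8.25 in cHet and 8.30 in cKO (exact permutation p = 0.0286 for each Cre group against control, on genes chosen from these values; p = 0.143 for cKO against cHet). The difference of cHet from control, 0.131, was 0.0775 after rescaling without mitochondrially encoded genes. That rescaling also sets equal library totals, and it moved the median log2 change of all genes for cHet against control from 0.0129 to -0.0394.

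**Figure D2:**
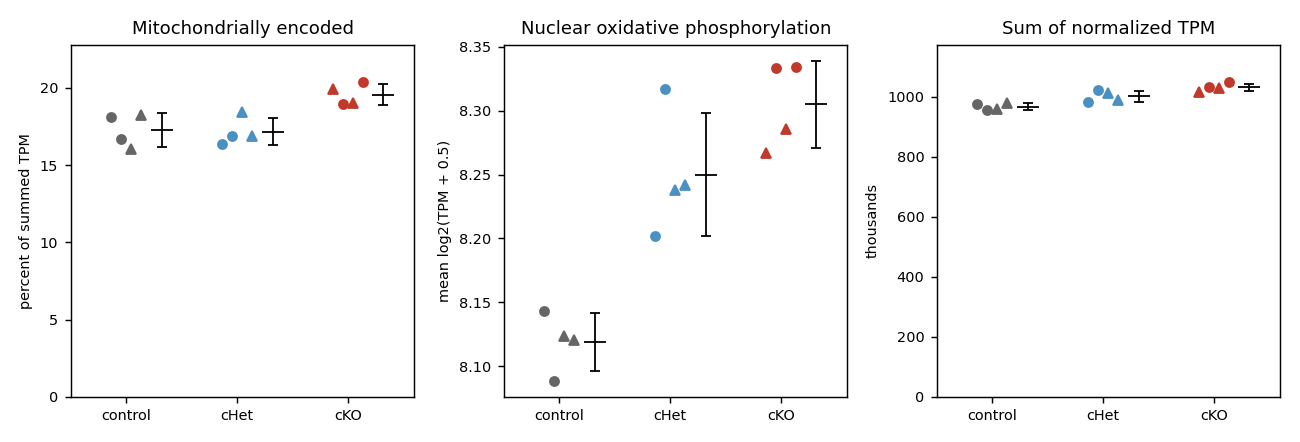
The share of summed TPM from mitochondrially encoded genes in percent, the mean log2(TPM + 0.5) of 79 nuclear oxidative phosphorylation genes (axis not from 0) and the sum of normalized TPM, per library (circles labelled male, triangles labelled female), with mean and SD of 4 libraries. The mitochondrial share averaged 17.3% in control, 17.2% in cHet and 19.6% in cKO.

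Other cell types were examined through their markers. Neuron genes rose in 3 of 16 cases, Rbfox3, Syn1 and Slc32a1 (4 adjusted over the list alone; camera adjusted p = 0.0567), and none of 12 motor neuron genes was called (camera adjusted p = 0.207). The call of Slc32a1 was lost in 7 of 23 alternatives (highest adjusted p 0.123). Ret had 40.7 ± 1.51 TPM in control and 43.4 ± 0.391 in cKO (SD, n = 4), and the log2 difference of Prph was 0.19 ± 0.07 (SE). No endothelial or pericyte gene of 12 (camera adjusted p = 0.984), blood gene of 5 (0.903) or leukocyte gene of 4 (0.674) was called. The leukocyte list has 12 members, most of them not measured. The meningeal fibroblast list had Dcn higher (1 of 7, camera adjusted p = 0.293) and the Schwann cell list Fxyd1 higher and Pmp22 lower (2 of 5, camera adjusted p = 0.404; Pmp22 lost in 4 of 23 alternatives). Of 8 ependymal genes Mia rose (camera adjusted p = 0.0281, and adjusted p = 0.465 with an estimated correlation). The list call was lost without control replicate 3 (adjusted p = 0.212) and without cKO replicate 1 (0.0821). Of 12 cervical and upper thoracic Hox genes Hoxb8 rose (5 adjusted over the list alone; camera adjusted p = 0.00275, and adjusted p = 0.252 with an estimated correlation), while none of 7 lumbosacral Hox genes was called (camera adjusted p = 0.758).

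Genes linked to TDP-43 loss were measured at gene level only. Of 10 genes known for cryptic exons when TDP-43 is lost, Adnp2 rose (log2 change 0.21 ± 0.06, limma adjusted p = 0.0483; camera adjusted p = 0.234), a call lost in 16 of 23 alternatives. Adjusted over the list alone, 1 of the 10 was higher and 1 lower. None of 11 long-intron targets was called (camera adjusted p = 0.907), with Dlgap1 at 34.6 ± 0.933 and 36.3 ± 1.23 TPM (SD, n = 4). No gene was called among 13 of ER stress (camera adjusted p = 0.0915), 5 of cell division (0.457; 10 in the list) or 10 immediate early genes (0.758).

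**Figure D3:**
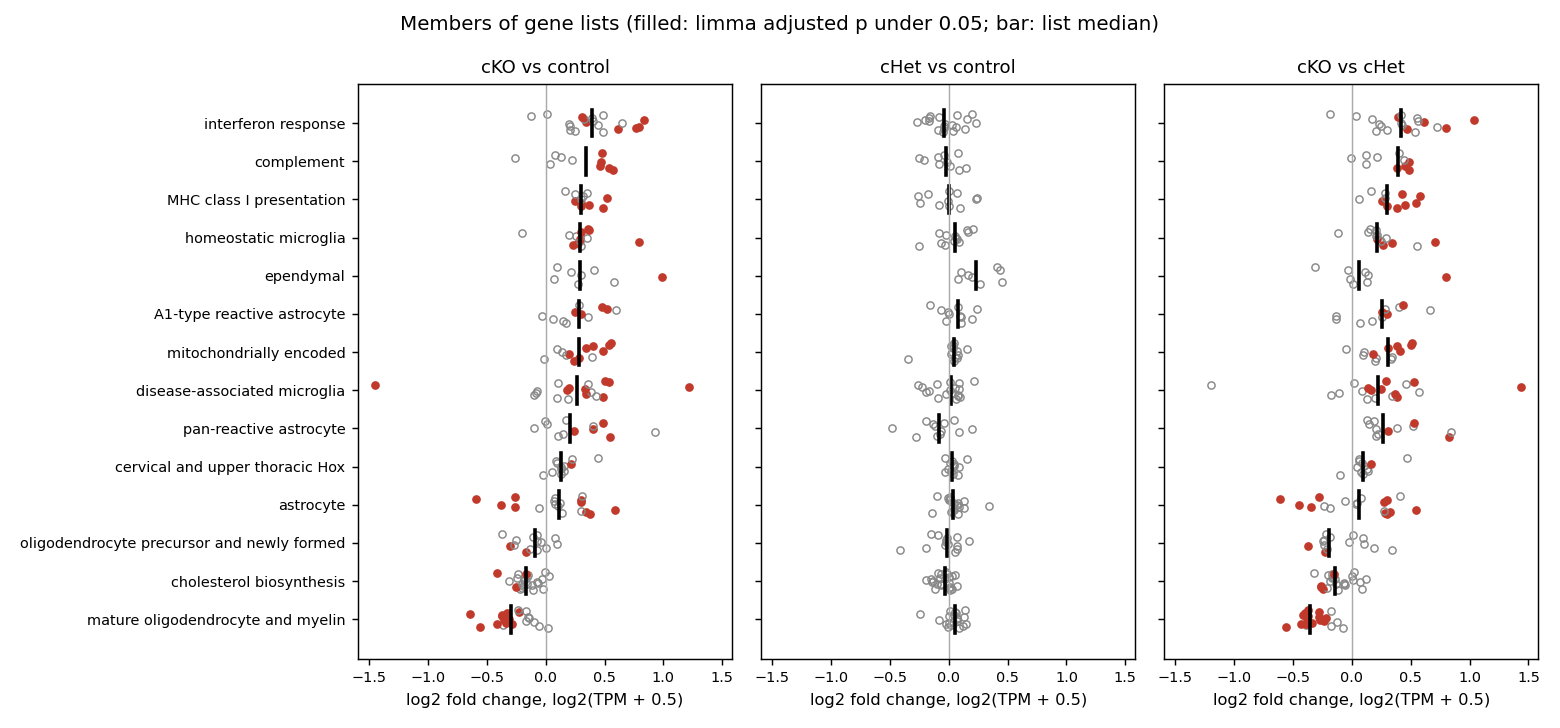
Log2 fold change on the log2(TPM + 0.5) scale (horizontal axis) of each measured member of 14 gene lists in the 3 comparisons; filled points have a limma adjusted p under 0.05 and black bars give list medians. In cKO against control the median was -0.30 for myelin genes and 0.35 for complement genes.

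The comparison of cHet with control asked whether deletion of a single allele had an effect. Limma called no gene of 15259, with a smallest adjusted p of 0.0857. At an unadjusted limma p under 0.05 were 1724 genes (11.3%), above the share of 0.05 that unchanged groups give on average. Genes are not independent, so this excess is not a test. In the authors' deposited table the likelihood ratio test gave 0 genes at a q under 0.05 and the Wald test gave 28, of which Usp31, Hspa8, Chchd2, Dmp1 and Slc5a3 had the smallest q, all higher in cHet. The 5 named genes with the smallest p were at these levels in control and cHet: Chchd2 at 490.1 ± 15.4 and 562 ± 4.81 TPM, Uqcrh, a subunit gene of respiratory complex III, at 793 ± 22.5 and 904 ± 26.1, Minos1 at 269.9 ± 6.20 and 315 ± 12.4, Plcd4 at 33.8 ± 0.921 and 39.2 ± 0.798, and Txnl4a at 23.8 ± 1.47 and 29.6 ± 0.885 (SD, n = 4). Gfap had a log2 difference of -0.06 ± 0.06 (limma adjusted p = 0.764). Of the 29 lists camera called only ER stress and the integrated stress response as higher in cHet (adjusted p = 0.0071), and adjusted p = 0.187 with an estimated correlation. None of its 13 members was called over all genes (2 adjusted over the list alone). Hspa5 was at 144 ± 7.48 and 194 ± 31.9 TPM and Creld2 at 15.5 ± 0.622 and 19.8 ± 2.92 TPM in control and cHet. Without cHet replicate 4 the camera adjusted p was 0.109. The myelin list had a camera adjusted p of 0.526, and the homeostatic microglia list 0.649. The simulation with known changes recovered 92% of changes of 1 and 64% of changes of 0.5 on the log2 scale for this comparison, so small effects could go uncalled.

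The comparison of cKO with cHet set 2 groups with Cre against each other. Gli1, Etnppl and Mc5r again fell, by 1.78, 1.54 and 1.48 on the log2 scale, and Qprt, Pm20d1, Slc25a34, Adamts9 and Gpnmb rose by 1.55, 1.51, 1.47, 1.42 and 1.44. Limma called 765 genes, 367 higher and 398 lower in cKO, of which 103 changed by at least 1.5-fold. Further rises were Ccnb1ip1 (log2 change 1.60 ± 0.40), Acox2 (1.48 ± 0.26), Vill (1.22 ± 0.31), Gfpt2, a gene of hexosamine synthesis (1.09 ± 0.11), and Papss2 (1.07 ± 0.12). Further falls were Car3 (-1.26 ± 0.17), the cystine transporter gene Slc7a11 (-1.10 ± 0.10), Ccdc33 (-1.10 ± 0.28), Ptgds (-1.03 ± 0.12), Itih3 (-0.99 ± 0.08), Fgl2 (-0.93 ± 0.07) and Rasal1 (-0.93 ± 0.12). Limma adjusted p values of these 20 genes were at or below 0.0461, that of Vill. The calls of Ccnb1ip1, Vill and Ccdc33 were lost in 11, 10 and 10 of 22 alternatives (highest adjusted p 0.106, 0.116 and 0.0974).

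Glul, the glutamine synthetase gene, was at 1086 ± 69.4 TPM in cHet and 795 ± 16.8 in cKO (SD, n = 4; limma adjusted p = 0.000174), and Slc1a3 fell by 0.61 while Atp1b2 and Slc1a2 rose by 0.54 and 0.30 on the log2 scale; 6 of 18 astrocyte genes rose and 4 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.195). Gfap rose by 0.30 ± 0.06 on the log2 scale (limma adjusted p = 0.0171; 0.0522 without cKO replicate 2). Called members numbered 3 of 12 for pan-reactive (6 adjusted over the list alone; camera adjusted p = 3.72e-06), 3 of 11 for A1-type (5; 0.000146), 4 of 13 for homeostatic microglia (8; 3.1e-07), 4 of 10 for complement (7; 2.38e-07) and 7 of 11 for MHC class I genes (9; 1.16e-09), all higher in cKO. Of 18 disease-associated microglia genes 8 rose (10 higher and 2 lower adjusted over the list alone; camera adjusted p = 3.85e-07). Trem2, a microglial receptor gene with a second annotated copy, was at 8.27 ± 0.511 TPM in cHet and 12.1 ± 0.869 in cKO. With an estimated correlation the adjusted p of these 6 lists lay between 0.00723 and 0.0344. Myelin genes fell in 15 of 20 cases (18 adjusted over the list alone; median log2 change -0.35; camera adjusted p = 1.98e-19, and adjusted p = 0.0344 with an estimated correlation), with Myrf at 56.1 ± 3.37 and 41.9 ± 1.11 TPM and Ermn at 169.9 ± 3.74 and 126 ± 11.1 TPM in cHet and cKO.

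The remaining lists called against cHet were lost with an estimated correlation. Interferon genes rose in 5 of 19 cases, among them Lgals3bp, Ifi27 and Oasl2 (12 adjusted over the list alone; camera adjusted p = 2.02e-09, and adjusted p = 0.0563 with an estimated correlation). Mitochondrially encoded genes rose in 6 of 13 (8 adjusted over the list alone; camera adjusted p = 2.02e-09, and adjusted p = 0.196 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 23, among them Fdps, Fdft1 and Srebf2 (7 adjusted over the list alone; camera adjusted p = 8.92e-05, and adjusted p = 0.429 with an estimated correlation), and these calls were lost in 7, 6 and 10 of 23 alternatives (highest adjusted p 0.0720, 0.0842 and 0.105). Oligodendrocyte precursor genes fell in 2 of 14 (2 adjusted over the list alone; camera adjusted p = 0.0328, and adjusted p = 0.429 with an estimated correlation). Cervical Hox genes had Hoxb8 higher (1 adjusted over the list alone; camera adjusted p = 0.00862, and adjusted p = 0.375 with an estimated correlation). Single called genes in lists that were not called were Emp1, Dcn, Mia, Cyr61, Syn1, Rbfox3 and Fxyd1, all higher in cKO, and Pmp22 and Synj2bp, both lower. Of these calls, those of Rbfox3, Dcn and Emp1 were lost in 15, 7 and 3 of 23 alternatives and that of Cyr61 in 10 of 22 (highest adjusted p of the 4 genes 0.130). No measured gene of the motor neuron, endothelial, blood, leukocyte, NF-kB, long-intron, ER stress, cell division or lumbosacral Hox lists was called.

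Of the genes called by limma, 589 were called in cKO against both control and cHet, 303 higher and 286 lower in both and 0 with opposite signs. Both comparisons use the same cKO libraries. In 20 draws simulated unchanged groups gave a mean of 0 genes in common, and independent lists of these lengths would share 21.1 higher and 12.9 lower genes. The simulated groups have no effects to call, and independent lists leave out the shared cKO libraries. Neither value is therefore a reference for the 589. The fold changes of cKO and cHet against the same controls correlated across genes, which are not independent replicates, at r = 0.438 where simulated unchanged groups gave 0.495. Their covariance was 0.0184 against a simulated 0.0131, and with the controls split into pairs the mean correlation was 0.0452. Over all genes 67.6% had the same sign in both, where simulated unchanged groups gave 66.7%.

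In the authors' deposited tables the likelihood ratio test gave 1687 genes at a q under 0.05 for cKO against control (1164 higher, 523 lower) and 674 for cKO against cHet (333 higher, 341 lower). Of these, 1163 and 575 were also called by limma, all in the same direction. The smallest q in the authors' deposited table for cKO against control belonged to Cxcl14, Dio2, Hsd11b1, Klhdc7a and Dmp1 among higher genes and to Kcnj16, Pex5l, Efnb3, Slc7a11 and Aebp1 among lower genes. In the authors' deposited table for cKO against cHet they were Adamts9, Cxcl14, Igfbp2, Ncan and Elovl2 (higher) and Pex5l, Fgl2, Kcnj16, Etnppl and Itih3 (lower). The authors' deposited q for Tardbp was 0.0176 against control and 0.0419 against cHet.

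Whether genotype effects differed between the sexes was tested with the labelled sex. Limma called 1 gene of 15259 for cKO against control, with 592 (3.88%) at an unadjusted p under 0.05, and 1 for cHet against control, with 849 (5.56%). These shares lie near the 0.05 that unchanged groups give on average. In both comparisons the called gene was a predicted gene, Gm16867, named after its values were seen. Control replicate 1 is labelled male and had 0.288 TPM of the Y-linked gene Ddx3y, where the other 5 libraries labelled male had 30.5 to 36.5 TPM, so its label is in doubt. Without it the controls hold a single library labelled male, so a count for the interaction would rest on that mouse and is not given. The genotype comparisons without control replicate 1 gave 1038 genes for cKO against control, 0 for cHet against control and 675 for cKO against cHet.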

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

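The sex interaction was planned; the tests of the sex label of control replicate 1, and the interaction without that library, were chosen only after the result was seen. For Gm16867, a predicted gene, males by label minus females on the log2 scale was -2.55 in control, 0.36 in cHet and 0.52 in cKO, so the gap was widest in control and of the other sign. The signed difference from control was 3.07 ± 0.29 for cKO (SE, limma adjusted p = 0.0305) and 2.91 ± 0.29 for cHet (limma adjusted p = 0.0485). Control replicates 1 and 2 held 1.13 and 1.20 TPM of it, control replicates 3 and 4 held 9.92 and 8.72 TPM, and the cKO and cHet libraries held 11.1 to 21.1 TPM. Control replicate 2 had Ddx3y at 34.3 TPM and control replicate 1 at 0.288 TPM. The low values of Gm16867 in control therefore did not follow Y transcripts.

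Control replicate 1, labelled male, had Ddx3y at 0.288 TPM and Eif2s3y at 0.658 TPM, where the 5 other libraries labelled male had at least 30.5 and 37.7 TPM. Against a swap with a library labelled female in this series, 0 of 6 such libraries held Y transcripts at male levels. Against a male without Y expression, its Eif2s3x was 107.8 TPM, where the other males had 67.6 to 74.2 and the females 102 to 119 TPM. A wrong sex label and a sample from outside the series cannot be told apart here, since its Tardbp of 181 TPM lay above the highest cKO library (151 TPM), which either leaves open.

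Outliers were sought among named genes and among measures of whole libraries, such as the sum of normalized TPM. Of 474 groups of 4 libraries, 38 (8.02%) held a library far from the other 3. Its gap to the nearest, relative to the group's range, exceeded Dixon's critical value, and chance gives about 1 in 20. All 38 were levels of named genes. In control these were Gfap (1092 TPM) and Hspb1 (54.3) in replicate 2, Selplg (17.6) and Hoxc10 (41.1) in replicate 1, and in replicate 3 Klri1 (3.15), Stard4 (22.03), S100a9 (4.45), Hoxa11 (2.42), Txnl4a (21.6), Pdgfrb (5.49) and Top2a (2.01), all in TPM. In cHet they were Slc25a34 (4.75), Nrxn3 (55.2), Hoxc6 (41.8) and Vill (1.41) in replicate 1, Aspa (112.7) in replicate 2, Lgals3 (13.1), Hspb1 (50.8) and mt-Nd5 (4519) in replicate 3, and Ptgds (1269), Cx3cr1 (14.6), Cyr61 (3.48), Txnl4a (28.3), Nfkbia (55.9) and Pdia4 (34.1) in replicate 4. In cKO they were Etnppl (9.05), Mia (21.6) and H2-Q4 (10.2) in replicate 1, Psmb8 (8.76), Cxcl10 (5.27) and Drp2 (12.5) in replicate 2, Serping1 (5.37), Emp1 (8.003), Ctsd (355) and Slc7a11 (1.36) in replicate 3, and Tardbp (140.5), Fdft1 (58.2) and Ccnb1ip1 (2.45) in replicate 4.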

How the results depend on the processing

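The merging of copies, the removal of a length trend and the sex interaction without control replicate 1 were chosen only after the result was seen. No call of a gene or list turned its direction. The balance of called genes for cKO against control did, from 63.9% higher to 36.3% higher after rescaling without mitochondrially encoded genes (54.9% after median-of-ratios rescaling). The count for cKO against control (1374) lay between 814 (without cKO replicate 2) and 1512 (without cHet replicate 4), and was 907 without control replicate 2, 890 without cKO replicate 4, 1276 with the length trend removed and 1341 with copies merged. For cKO against cHet (765) it lay between 526 (only those groups in the fit; 532 without cKO replicate 4) and 777 (median-of-ratios rescaling). For cHet against control limma gave 0 genes (1724 at an unadjusted p under 0.05), 2 without a filter, 1 without control replicate 2 and 0 without control replicate 1. The sex interaction of cKO against control gave 1 gene, 0 with a pseudocount of 1 and 22 without a filter. Without control replicate 1 a single control library labelled male is left, so that count is not given. The authors' deposited likelihood ratio q gave 624 genes under 0.01 and 2554 under 0.1 for cKO against control, 1 under 0.1 for cHet against control, and 261 and 1027 for cKO against cHet (Wald q 1187 and 2299, 58 under 0.1, and 578 and 1149). The covariance of the cKO and cHet effects, 0.0184, was 0.00524 above simulation. With the controls split, so that the comparisons share no library, the covariance was 0.000406 to 0.00375, below that excess in every split.

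With an estimated correlation, adjusted p values for cKO against control were 0.307 (astrocyte), 0.133 (interferon), 0.0835 (myelin), 0.256 (oligodendrocyte precursor), 0.254 (cholesterol), 0.465 (ependymal), 0.211 (mitochondrially encoded) and 0.252 (cervical Hox). They were 0.187 for ER stress in cHet, and for cKO against cHet 0.0563 (interferon), 0.429 (oligodendrocyte precursor and cholesterol), 0.196 (mitochondrially encoded) and 0.375 (cervical Hox). With fry they were 0.0778 (ependymal, against control), and against cHet 0.0861 (oligodendrocyte precursor), 0.132 (cholesterol) and 0.0565 (cervical Hox). The ependymal list ranged from 0.00172 (without control replicate 2) to 0.212 (without control replicate 3), with 0.0821 without cKO replicate 1. ER stress in cHet ranged from 0.00117 (without cHet replicate 3) to 0.109 (without cHet replicate 4). Against cHet, precursor genes ranged from 0.0203 (without cKO replicate 1) to 0.165 (without cHet replicate 4), with 0.0528 and 0.0930 without cKO replicates 2 and 4, and cervical Hox genes from 0.00156 (without cHet replicate 2) to 0.0904 (without cHet replicate 4). Tardbp against cHet ranged from -0.24 (without cHet replicate 4) to -0.18 (without cKO replicate 4, adjusted p = 0.0522). Lists that were not called passed in 26 cases, 15 of them neurons. Calls of genes that the naming rule takes, Tardbp aside, were lost in 211 cases, most often Adnp2 (16 of 23), Rbfox3 against cHet (15) and Gfap and Ccnb1ip1 (11 each). The cause was not tested. No paired analysis was possible because the labels pair no mice between groups. Read depth is unknown.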

Other observations

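The lists of glycogen and glycolysis genes and of hedgehog genes, and the tests of the oxidative phosphorylation and myelin patterns, were chosen only after the result was seen; the splits of the libraries were planned. Of 19 glycogen and glycolysis genes 11 rose and none fell in cKO against control (median log2 change 0.17), among them the glycogen phosphorylase gene Pygm (37.3 to 57.4 TPM), Pfkm (241 to 328 TPM) and Ldha (85.0 to 110.0 TPM). Camera gave an adjusted p of 1.06e-11, and 0.0453 with an estimated correlation. The list was drawn up after values of these libraries were seen, so these p values describe the same data and do not test whether the genes move together; no independent samples were at hand. Against cHet 6 rose (0.0326 with an estimated correlation), and cHet against control had none called.

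After the fall of Gli1, the hypothesis that hedgehog pathway genes move together in cKO was tested on 11 genes and was not borne out (camera adjusted p = 0.600, and 0.597 with an estimated correlation). Gli1 and Hhip (log2 change -0.50) were called lower and Boc (0.30) higher.

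Nuclear oxidative phosphorylation genes (79) had a higher mean log2 level in cHet than in control by 0.131 and in cKO by 0.186 (exact permutation p = 0.0286 each), with 45 called higher in cKO against control and 0 in cHet against control. Scaling between libraries is argued against as the whole cause, since the cHet difference was 0.119 after median-of-ratios rescaling and 0.0775 without mitochondrially encoded genes. A length trend is also argued against as the whole cause, with 0.102 after its removal. The exact permutation p was 0.0286 for all, but the genes were chosen from these libraries, so it is not a test. Their median transcript length was 595.5 bases, against 1416 for all tested genes, so a length effect may be incompletely removed. The presence of Cre, a separate origin of the controls and the loss of an allele cannot be told apart: cKO minus cHet was 0.0552 (exact permutation p = 0.143), and no group had Cre without a floxed allele.

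Of 20 myelin genes 11 were called lower in cKO against control (list adjusted p = 0.0835 with an estimated correlation). An equal fall of all members is argued against by the SD of log2 change over members, 0.162, where the highest of 34 other splits of group-centred libraries gave 0.0644. Whole cord does not show how much RNA of each member comes from other cells. An equal loss of oligodendrocyte RNA therefore stays open, as does a partial loss. Scaling between libraries moves all genes alike, and is argued against by the gap of the list median to the median of all genes, -0.31, where the largest gap in 34 other splits was 0.0833 and 19 of 20 members lay below 0. A different level of the cord stays open, since the cervical minus lumbosacral Hox difference was 0.0400 (exact permutation p = 0.8). Loss of Tardbp, the difference between the genotype groups by design, stays open. No test separated it from batch or litter, which the labels do not give. Against cHet, which also carries Cre, 15 of 20 members were called lower in cKO (camera adjusted p = 0.0344 with an estimated correlation). In cHet against control no member was called.

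The splits argue against chance for the counts of cKO against control and of cKO against cHet, without excluding it. Only the real split, 1 of 35 and the smallest share possible, gave as many genes as the 1374 (highest other split 3) and the 765 (highest other 6). The other splits mix genotypes within a group, which widens the spread, so their low counts are partly built in. The labels give no batch or litter, so the splits cannot separate genotype from these. For cHet against control the real count by limma was 0 (1724 at an unadjusted p under 0.05; 0 by the authors' deposited likelihood ratio test and 28 by their Wald test; highest other split 1). All 35 splits give at least 0 by construction, so the splits say nothing about chance there.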
